A study of Mus musculus with 8 samples.

How the data were processed

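The series measured polyadenylated RNA in brown adipose tissue of 20-week-old C57BL/6N mice on chow. The 8 libraries form 2 groups of 4. The control group (WT) carries floxed alleles of Adcy3, the gene of adenylyl cyclase 3, an enzyme that makes cyclic AMP. The knockout group (cKO) carries the same floxed alleles and a Cre recombinase driven by the adiponectin gene promoter (Adipoq-Cre), which removes the floxed part in adipocytes. The sample labels name the tissue as interscapular, whereas the design text calls it inguinal, and the sample labels were followed. Paired-end libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols, and sequenced on a NovaSeq6000, per the design text.

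The authors deposited 1 table of estimated counts, with 1 row for each of 54385 Ensembl gene identifiers and 1 column per library. StringTie, Salmon and edgeR are named in the submitters' processing notes without versions or settings, together with the genome build GRCm38. The annotation release, the strand setting and any filters are not given in the sources used here. Salmon-type counts are estimates that divide a read among the transcripts it could come from, so counts of near-identical genes depend on that division. Every column matched 1 library through the identifier in its label.

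Libraries were grouped by their titles. The title of WT replicate 4 calls it a control, but its genotype entry carries the Cre. It entered as a control, and the gene and list tests were repeated without it and with it moved to the knockout group. The labels number replicates 1 to 4 in each group and do not say that each library came from a separate animal, so p-values measure the spread between these libraries.

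Symbols, positions and transcript sequences came from the GENCODE annotation of GRCm38 (release M21), which named 54131 of the identifiers (99.5%). The estimated counts were rounded to whole numbers. No pair of libraries of the same group agreed within sampling noise, the smallest chi-square per degree of freedom being 14.5 over genes with at least 20 counts in the pair. Pairs of a WT and a cKO library were not compared in this way. Totals ran from 10713043 to 32437214 estimated counts per library.

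Genes were kept with edgeR's filterByExpr, which left 14553. Libraries were scaled by TMM, and groups were compared with edgeR's robust quasi-likelihood test (edgeR 4.0.16, R 4.3.3) at a Benjamini-Hochberg adjusted p of 0.05, with group as the only term. The design, the 32 gene lists and the rule for named genes were fixed before the data were examined. That rule names Adcy3, up to 10 called genes per direction with the largest change, and members of each list. Called genes qualify with at least 1 CPM on average, no overlap between groups and a symbol other than a predicted gene. From each list it names up to 4 called members or, where none was called, up to 2 with the highest mean. Only Adcy3 and Rpl23a-ps3 qualify as called genes, so the 8 other called genes, and all members named because a list-alone adjustment or another tool called them, were chosen after their values were seen.

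The 30 lists with at least 5 measured members were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, served as alternatives. Estimated correlations ran from -0.0641 to 0.987 over the lists. Where the genes of a list are correlated above the preset, p-values of camera with the preset are too small. CPM values are TMM-scaled, log2 CPM carries a prior count of 2, and errors after ± are SDs over 4 libraries unless marked SE. Intervals are at 95%. A gene with 0 counts in a group is given as a lower bound against a floor of 3 counts over the whole group, and floors and counting intervals cover counting error only.

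To find genes that share reads, the share of each gene's 31-base sequences found in the transcripts of any other gene was computed (Python 3.11.15). Genes sharing at least 50% count here as mostly shared.

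The test was tried on simulated data for this comparison, with counts drawn for the 14553 genes at the real depths and spread. It recovered 7.46% of 67 genes changed 1.5-fold, 55.2% of 67 changed 2-fold and 87.9% of 66 changed 4-fold. Of its 110 calls, 100 were of these genes, 1 was in a list shifted by 0.5 log2 units, and 9 were false. Changes of 1.5-fold are therefore mostly missed with 4 libraries per group, and many of 2-fold as well. The real data gave 10 calls, and fewer calls make the adjusted threshold stricter, so recovery there may be lower.

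The alternatives planned beforehand were DESeq2 size factors, upper quartile factors, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom with and without library quality weights, no filter, a filter of 1 CPM in 4 libraries, a replicate block, each library left out, WT replicate 4 moved, and mitochondrially encoded genes removed. Added after seeing the data were a skeletal muscle score as a covariate, leaving out the libraries richest in muscle transcripts (WT replicate 4 and cKO replicate 1), counts summed over near-identical genes, only mostly unshared genes, and removal of a trend with transcript length. The values of 1 gene that the rule names are not reported here. Isoforms were not analysed here, since the table holds 1 row per gene.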

Results

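Brown adipose tissue of mice with and without Adcy3 in adipocytes was profiled by RNA sequencing, with 4 control (WT) and 4 knockout (cKO) libraries. Brown fat burns fuel for heat under adrenergic drive, which acts through cyclic AMP, and the title of the series asks how Adcy3 and a cold-induced truncated form of it set brown fat function. The comparison here is cKO against WT on chow at 20 weeks of age. WT libraries held 32437214, 13393198, 18423921 and 12977094 estimated counts in total and cKO libraries 15034847, 10713043, 16243318 and 14171711.

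Adcy3 transcript was lower in every cKO library than in any WT library. It stood at 103 ± 27.4 CPM in WT and 21.4 ± 3.03 CPM in cKO (SD, n = 4 each), so that cKO tissue kept 20.9% of the WT level. The fitted decrease was 4.79-fold (95% interval 3.49 to 6.57), a log2 fold change of -2.26 ± 0.21 (SE, edgeR adjusted p = 0.000925). WT replicates 1 to 4 held 112, 118, 61.7 and 118 CPM, and cKO replicates 1 to 4 held 17.95, 20.9, 25.3 and 21.5 CPM. The library titled WT replicate 4, whose genotype entry carries the Cre, therefore lay at the level of the other controls. Adcy3 (ENSMUSG00000020654) is a protein-coding gene on chromosome 12, 4133103 to 4213525 on the plus strand of GRCm38. It overlaps Cenpo on the minus strand, with which it shares 20.0% of its 31-base sequences, and Cenpo was at 5.65 ± 1.14 CPM in WT and 5.15 ± 1.59 CPM in cKO (log2 fold change -0.13, edgeR adjusted p = 0.968). Counts per gene do not separate full-length from truncated Adcy3 transcripts, nor the floxed exons from the rest.

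None of the 7 other measured adenylyl cyclases passed edgeR's test, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Adcy6, the most abundant in this tissue, stood at 211 ± 28.6 CPM in WT and 217 ± 26.5 CPM in cKO (log2 fold change 0.05, 95% interval -0.24 to 0.33). Adcy4 had 23.2 ± 7.52 and 19.9 ± 4.22 CPM, Adcy9 19.3 ± 8.27 and 20.2 ± 7.39 CPM, and Adcy5 10.4 ± 2.18 and 9.97 ± 3.36 CPM. Over the list of adenylyl cyclases, 1 member was called over all genes tested and 1 when adjusted over the list alone, Adcy3 in both cases, and camera did not call the list (adjusted p = 0.385).

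**Figure D1:**
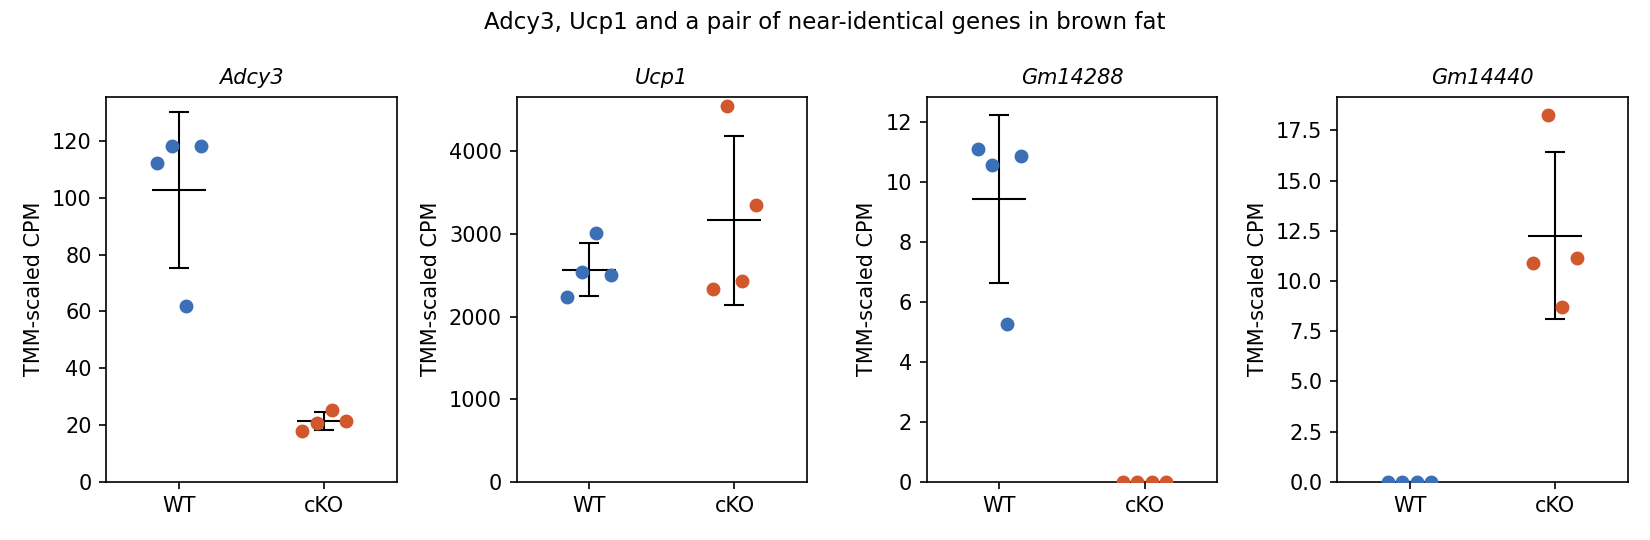
TMM-scaled CPM (y axes, starting at 0) of Adcy3, Ucp1, Gm14288 and Gm14440 in the 4 WT and 4 cKO libraries; each point is a library, horizontal bars are means and whiskers SDs. Adcy3 lies at 61.7 to 118 CPM in WT and 17.95 to 25.3 CPM in cKO, the groups overlap for Ucp1, and Gm14288 and Gm14440 are each at 0 in every library of 1 group.

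Outside Adcy3, few genes passed edgeR's test. Of 14553 genes tested, edgeR called 10, of which 7 were higher and 3 lower in cKO. At an unadjusted p under 0.05 there were 815 genes, against 728 by chance, and the groups did not overlap for 510 genes (3.50%, against 2.86% by chance). DESeq2 called 46 genes, 20 higher and 26 lower, including all 10, and edgeR without a count filter called 93, also including all 10. Among the 351 measured genes of the 32 lists, edgeR and limma-voom each called only Adcy3. Of the 351, 29 had an unadjusted edgeR p under 0.05. Besides Adcy3, DESeq2 called 6 of them (Prdm16, G0s2, mt-Nd1, mt-Nd2, mt-Atp8 and Eif4a2), limma-voom with library quality weights called mt-Atp8, and edgeR without a count filter called 6 (Prdm16, mt-Nd2, mt-Atp8, Eif4a2, Nr4a2 and Cebpb). Calls within lists are those of edgeR below unless another tool is named.

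The other 9 called genes were pseudogenes, predicted genes or unnamed transcripts, and each shared 57.9% to 100% of its 31-base sequences with other genes. Estimated counts cannot place such reads with certainty, so their values are uncertain. Gm14288 and Gm14440, predicted protein-coding genes on chromosome 2 at 175789357 to 175801093 (minus strand) and 175275125 to 175286805 (plus strand), share all of their sequence with other genes, mostly with each other. Gm14288 had 755 counts in WT and 0 in cKO, at least 183-fold lower (edgeR adjusted p = 0.000113). Gm14440 had 0 counts in WT and 631 in cKO, at least 289-fold higher (edgeR adjusted p = 4.02e-05). Their sum did not differ by the test, with 9.45 ± 2.80 CPM in WT and 12.3 ± 4.16 CPM in cKO (log2 fold change 0.37, 95% interval -0.25 to 0.98, edgeR adjusted p = 0.901).

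Rpl23a-ps3, a processed pseudogene of the ribosomal protein gene Rpl23a (chromosome 14, 34170655 to 34171122, plus strand), had 0 counts in WT and 1124 in cKO. It was at least 515-fold higher (edgeR adjusted p = 0.0109), whereas Rpl23a itself had a log2 fold change of -0.03 (edgeR adjusted p = 0.983). Gm13772, close in sequence to Gm10053 and the cytochrome c gene Cycs, was at least 286-fold higher in cKO (edgeR adjusted p = 0.000279). Gm17538, a processed pseudogene on chromosome 17 that shares 89.2% of its sequence with the deubiquitinase gene Usp9x, was at least 43.1-fold higher (edgeR adjusted p = 0.00372). Gm11868, a copy of Cyb5r4, had 1 count in WT and 236 in cKO, a ratio of 325 with a counting interval of 57.7 to 12870 (edgeR adjusted p = 3.17e-05). Gm7049 and Gm48795, which overlap on chromosome 13 and resemble the malic enzyme gene Me1, rose from 0.216 ± 0.251 to 18.1 ± 5.80 CPM and from 0.324 ± 0.172 to 38.3 ± 9.78 CPM (edgeR adjusted p = 0.00481 and 9.08e-06). Me1 stood at 1155 ± 590 CPM in WT and 1207 ± 294 CPM in cKO (log2 fold change 0.06). Gm20390, a transcript spanning Nme1 and Nme2 on chromosome 11, fell from 20.7 ± 1.28 to 9.28 ± 2.13 CPM (log2 fold change -1.15 ± 0.16 (SE), edgeR adjusted p = 0.0168). Nme2 had 138 ± 25.4 and 106 ± 8.82 CPM and Nme1 31.9 ± 5.68 and 25.5 ± 2.76 CPM (log2 fold changes -0.38 and -0.32, edgeR adjusted p = 0.882 and 0.883, unadjusted p = 0.0139 and 0.0391).

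When counts were summed over genes that share at least 50% of their sequence, edgeR called 1 gene, Adcy3. The same held when only mostly unshared genes were tested, but that setting leaves out the other 9 in advance. Summing adds several of the 9 to far more abundant copies, such as Gm17538 (1.78 CPM in cKO) to Usp9x (116 CPM in cKO). Their calls could then hardly persist, so their loss does not show that these changes cancel between copies. Among the 9, 3 lost their calls with 1 library left out, while their levels moved little. Gm20390 (log2 fold change -1.17 to -1.10) lost its call without any 1 of WT replicates 1, 2, 3 and 4 (edgeR adjusted p = 0.0604, 0.0679, 0.0714 and 0.0701) or without cKO replicate 4 (0.144). Rpl23a-ps3, at 0 counts in every WT library, lost it without WT replicate 3 (0.0576) or cKO replicate 4 (0.157), and Gm7049 without WT replicate 3 (0.0727, log2 fold change 6.50 against 6.48 with all libraries).

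Genes of heat production did not pass edgeR's test over all genes. Ucp1, the uncoupling protein of brown fat mitochondria, stood at 2571 ± 324 CPM in WT and 3167 ± 1025 CPM in cKO (log2 fold change 0.30, 95% interval -0.14 to 0.74, edgeR adjusted p = 0.898). Cidea, a lipid droplet protein abundant in brown fat, had 1428 ± 197 and 1307 ± 242 CPM. Of the 23 measured thermogenic genes, 17 had positive and 6 negative log2 fold changes with a median of 0.23. By edgeR, 4 had an unadjusted p under 0.05, 0 were called over all genes and 1, Prdm16, when adjusted over the list alone. DESeq2 and edgeR without a count filter each called Prdm16 over all genes. Prdm16, a transcriptional regulator of brown fat identity, stood at 17.8 ± 3.78 CPM in WT and 30.7 ± 4.03 CPM in cKO without overlap (log2 fold change 0.79, edgeR adjusted p = 0.242 over all genes). Camera did not call the list (adjusted p = 0.0612). It did under 8 of its 24 alternatives, among them those without WT replicate 1 (median 0.16, camera adjusted p = 0.0196), WT replicate 2 (0.26, 0.0375) or cKO replicate 1 (0.27, 0.00344). Alternative thermogenic cycles (median -0.01 over 9 genes, camera adjusted p = 0.584) included Atp2a2 with 229 ± 100 and 325 ± 147 CPM and Ckmt2 with 18.4 ± 28.6 and 35.7 ± 46.5 CPM, and both are also muscle transcripts.

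No component of adrenergic and cyclic AMP signalling passed the test. Of 26 measured members, edgeR called 0 over all genes and 0 when adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. The median log2 fold change was 0.04 (camera adjusted p = 0.382). Gnas, which encodes the stimulatory G protein subunit, had 1793 ± 179 CPM in WT and 1708 ± 214 CPM in cKO, and Prkar2b, a regulatory subunit of protein kinase A, 1025 ± 178 and 1066 ± 135 CPM. Cyclic AMP-inducible genes had a median of 0.19 over 14 members, with 3 at an unadjusted p under 0.05 and 0 called either way by edgeR or by DESeq2 over all genes, while edgeR without a count filter called Nr4a2 (camera adjusted p = 0.293). With WT replicate 4 moved to cKO by its genotype entry, camera called both lists, the signalling components at a median of 0.12 (adjusted p = 0.0351) and the inducible genes at 0.39 (adjusted p = 0.0176). Among them Dio2, which activates thyroid hormone, had 100.4 ± 34.1 CPM in WT and 162 ± 55.1 CPM in cKO (log2 fold change 0.69, 95% interval -0.12 to 1.497), and Per1 101.8 ± 11.5 and 77.6 ± 13.7 CPM (log2 fold change -0.39, edgeR adjusted p = 0.882).

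Camera called 3 of the 30 tested lists, all higher in cKO, and called 0 with an estimated correlation. Mitochondrially encoded subunits of oxidative phosphorylation had a median log2 fold change of 0.36, with 12 of 13 members positive (camera adjusted p = 2.96e-08, but adjusted p = 0.338 with an estimated correlation). By edgeR 6 had an unadjusted p under 0.05, 0 were called over all genes and 4 were when adjusted over the list alone, namely mt-Nd1, mt-Nd2, mt-Atp8 and mt-Atp6. Over all genes DESeq2 called mt-Nd1, mt-Nd2 and mt-Atp8, edgeR without a count filter mt-Nd2 and mt-Atp8, and limma-voom with quality weights mt-Atp8. mt-Atp6 stood at 27812 ± 1739 CPM in WT and 35690 ± 3784 CPM in cKO, and mt-Co1 at 54849 ± 4726 and 62857 ± 1940 CPM. Transcripts of the mitochondrial genome made up 26.2% ± 1.49 of counts in WT and 30.2% ± 2.31 in cKO (two-sided exact permutation p = 0.0857, n = 4 each). Nuclear subunits of the same complexes did not share the direction, with a median of -0.07, 14 of 20 negative, 0 at an unadjusted edgeR p under 0.05, and 0 called by edgeR either way or by DESeq2 (camera adjusted p = 0.319). Among them Atp5b had 4078 ± 169 and 3930 ± 204 CPM and Atp5a1 2647 ± 193 and 2566 ± 84.1 CPM.

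Heat shock genes, which encode chaperones, had a median log2 fold change of 0.42, all 7 positive, 1 at an unadjusted edgeR p under 0.05, and 0 called by edgeR either way or by DESeq2 (camera adjusted p = 0.00235, but adjusted p = 0.846 with an estimated correlation). Hspa8 stood at 1018 ± 190 CPM in WT and 1254 ± 284 CPM in cKO, and Hsp90aa1 at 311 ± 48.2 and 405 ± 91.9 CPM. The genes beside Adipoq on chromosome 16 had a median of 0.39, all 8 positive (camera adjusted p = 0.00516, but adjusted p = 0.338 with an estimated correlation). The mean log2 CPM of these genes overlapped between groups (exact permutation p = 0.171). In that list edgeR gave 3 genes at an unadjusted p under 0.05, called 0 over all genes and 3 when adjusted over the list alone, namely Rfc4, Eif4a2 and Kng2. DESeq2 and edgeR without a count filter each called Eif4a2 over all genes. The list lost its call without cKO replicate 3 (median 0.14, camera adjusted p = 0.0729) and with WT replicate 4 moved to cKO (median 0.16, camera adjusted p = 0.0701). Adipoq itself had 529 ± 80.6 and 521 ± 112 CPM. The genes beside Adcy3 had a median of 0.06 (camera adjusted p = 0.702).

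**Figure D2:**
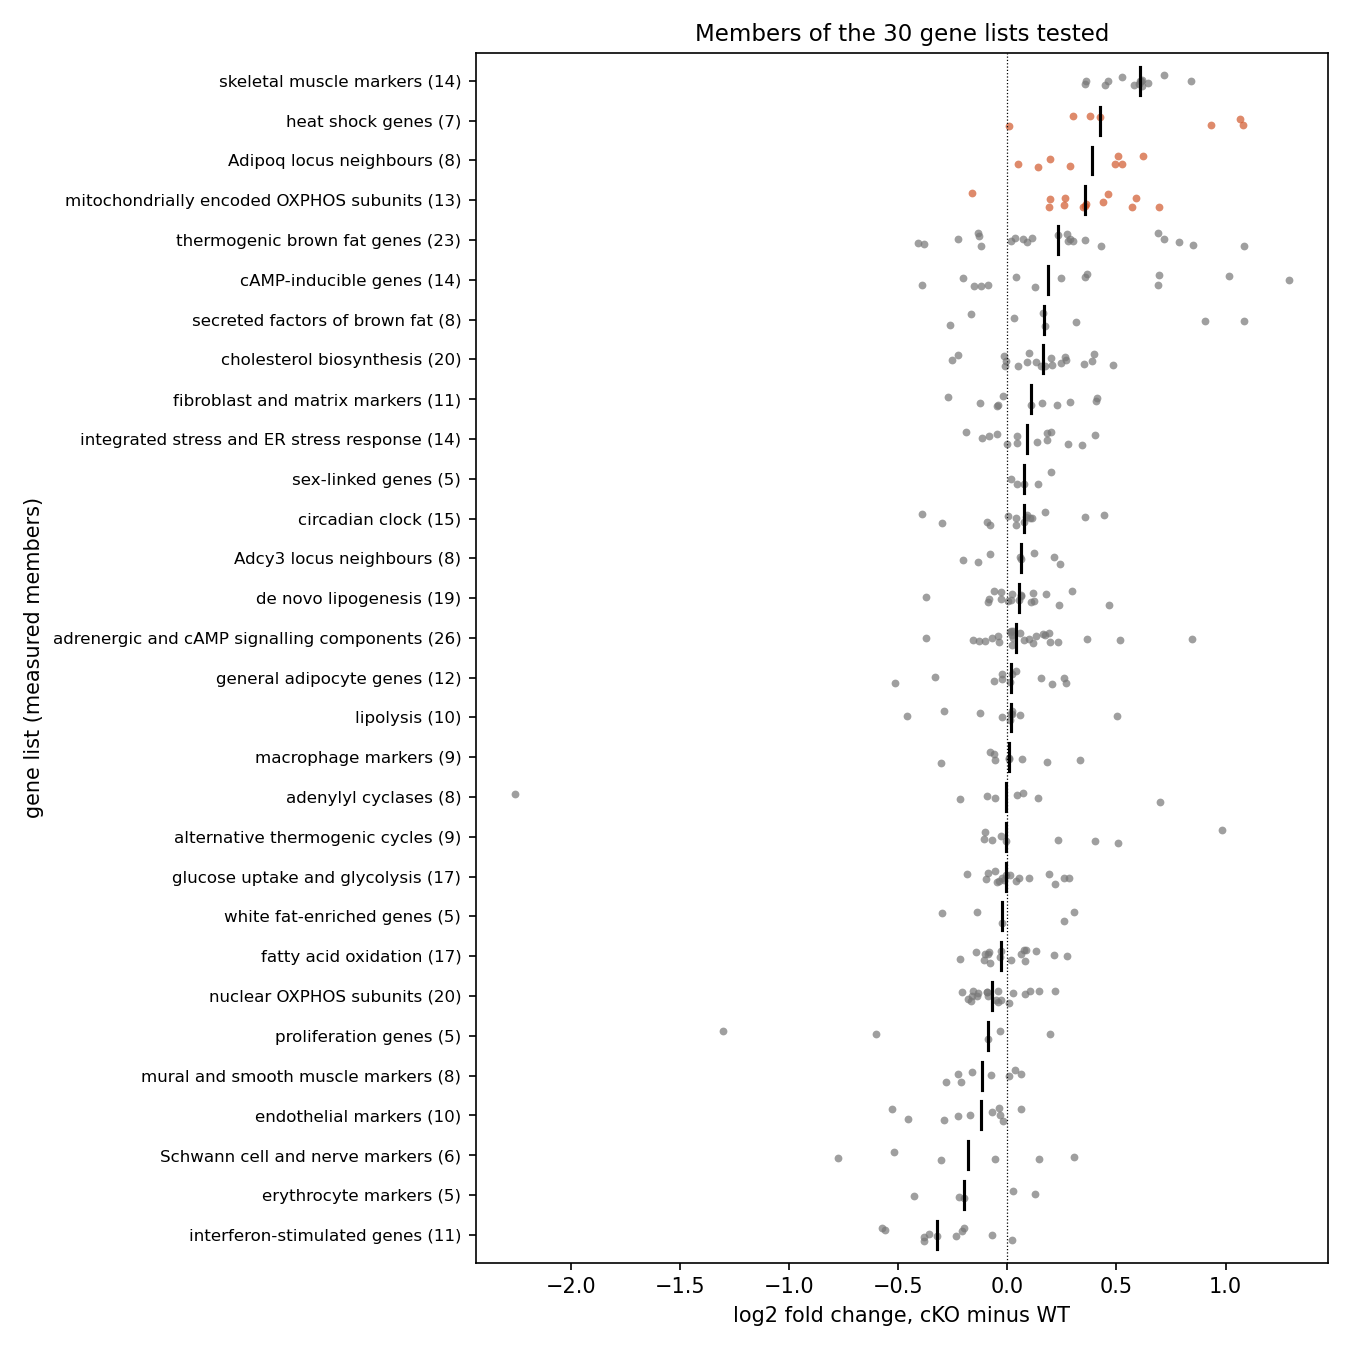
Log2 fold change of cKO against WT (x axis) for each measured member of the 30 gene lists tested (y axis, number of members in brackets); each point is a gene, black bars are medians, and lists called by camera with the preset correlation are orange. Adcy3 is the point at -2.26 among the adenylyl cyclases, and the medians of the called lists are 0.36, 0.39 and 0.42.

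Over all genes, edgeR called 0 of the 83 measured genes of lipid and glucose metabolism, with 5 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 1, G0s2. Lipogenic genes, among the most abundant transcripts of this tissue, had a median log2 fold change of 0.06 over 19 members (camera adjusted p = 0.426; without WT replicate 1 the list was called, with a median of 0.23 and adjusted p = 0.00258), with Scd1 at 50383 ± 9502 and 51191 ± 16530 CPM and Fasn at 25674 ± 6822 and 25745 ± 3538 CPM. Lipolysis genes had a median of 0.02 over 10 members (camera adjusted p = 0.543), with Pnpla2, the first lipase of triglyceride breakdown, at 2471 ± 224 and 2502 ± 367 CPM and Fabp4 at 5876 ± 463 and 5783 ± 1004 CPM. G0s2, an inhibitor of that lipase, was called when adjusted over the list alone (353 ± 46.9 CPM in WT, 257 ± 4.45 CPM in cKO, edgeR adjusted p = 0.497 over all genes). Cholesterol synthesis genes had a median of 0.16 with 15 of 20 positive (camera adjusted p = 0.0612). The list was called under 6 of its 24 alternatives, among them those without WT replicate 1 (median 0.34, camera adjusted p = 5.01e-05) or cKO replicate 1 (0.17, 0.0200). It held Insig1 at 546 ± 101 and 565 ± 59.6 CPM and Hmgcs1 at 162 ± 14.1 and 173 ± 21.2 CPM. Fatty acid oxidation (median -0.03 over 17, camera adjusted p = 0.894) and glucose uptake and glycolysis (median -0.01 over 17, camera adjusted p = 0.543) were also not called. Hadhb had 2843 ± 376 and 3116 ± 276 CPM, Acadl 1874 ± 233 and 1980 ± 306 CPM, Aldoa 3721 ± 454 and 3986 ± 466 CPM and Eno1 2911 ± 408 and 2938 ± 99.9 CPM. Apart from G0s2, edgeR called 0 members of these 5 lists when adjusted over the list alone.

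Adipocyte identity genes had a median of 0.02 over 12 members (camera adjusted p = 0.719), with Lpl at 3372 ± 176 and 4057 ± 991 CPM. White fat-enriched genes had a median of -0.03 over 5 (camera adjusted p = 0.719), with Lep at 76.9 ± 24.5 and 75.6 ± 33.9 CPM and Retn at 40.9 ± 5.58 and 48.8 ± 11.2 CPM. Secreted factors (median 0.17 over 8, camera adjusted p = 0.305) included Vegfa with 333 ± 59.1 and 376 ± 52.6 CPM and Nrg4 with 94.8 ± 17.6 and 106 ± 11.6 CPM. Stress response genes (median 0.09 over 14, camera adjusted p = 0.382) included Hspa5 with 208 ± 37.2 and 235 ± 26.8 CPM and Hsp90b1 with 178 ± 17.6 and 196 ± 24.6 CPM. Clock genes (median 0.07 over 15, camera adjusted p = 0.674) included Tef with 247 ± 24.8 and 254 ± 42.9 CPM and Nr1d1 with 139 ± 11.1 and 130 ± 26.7 CPM. Of the 54 genes of these 5 lists edgeR called 0 over all genes and 0 when adjusted over the list alone, with 3 at an unadjusted p under 0.05. DESeq2 called 0, and edgeR without a count filter called Cebpb.

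Under the planned TMM scaling and count filter, with libraries grouped by title, camera called no list of markers of another cell type, but skeletal muscle transcripts varied widely within both groups. The mean log2 CPM of 14 muscle genes ran from 1.59 (WT replicate 1) to 9.08 (cKO replicate 1), and these genes took 0.00737% to 1.11% of counts. Myh4, a fast muscle myosin, ranged from 9.92 to 2226 CPM in WT and from 39.2 to 2714 CPM in cKO, and Atp2a1 from 6.81 to 1683 and from 23.9 to 1993 CPM. The muscle score was 5.35 ± 3.06 in WT and 6.61 ± 2.41 in cKO (two-sided exact permutation p = 0.543, n = 4 each), and all 14 log2 fold changes were positive with a median of 0.61 (camera adjusted p = 0.0612, and adjusted p = 0.846 with an estimated correlation). Camera called this list under 7 of its 24 alternatives, 4 of them being upper quartile factors (median 0.61, camera adjusted p = 0.0483), no count filter (0.60, 0.0254), WT replicate 4 moved to cKO (2.54, 1.62e-06) and the 2 libraries richest in muscle left out (1.12, 0.0179). It was also called without WT replicate 2 (0.50, 0.0296), WT replicate 4 (2.28, 8.83e-05) or cKO replicate 3 (0.99, 0.000235). The first principal component, with 39.1% of the variance, followed the score over the 8 libraries (Pearson r = 0.970, exact permutation p = 2.48e-05; Spearman rho = 1.00, exact permutation p = 4.96e-05). Without the 2 libraries whose scores lay farthest from the median, r was 0.997, and this was the 1 relation tested across libraries. The 14 muscle genes also entered the component, so part of the relation is built in. With the score as a covariate, edgeR called 9 genes, all among the 10.

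**Figure D3:**
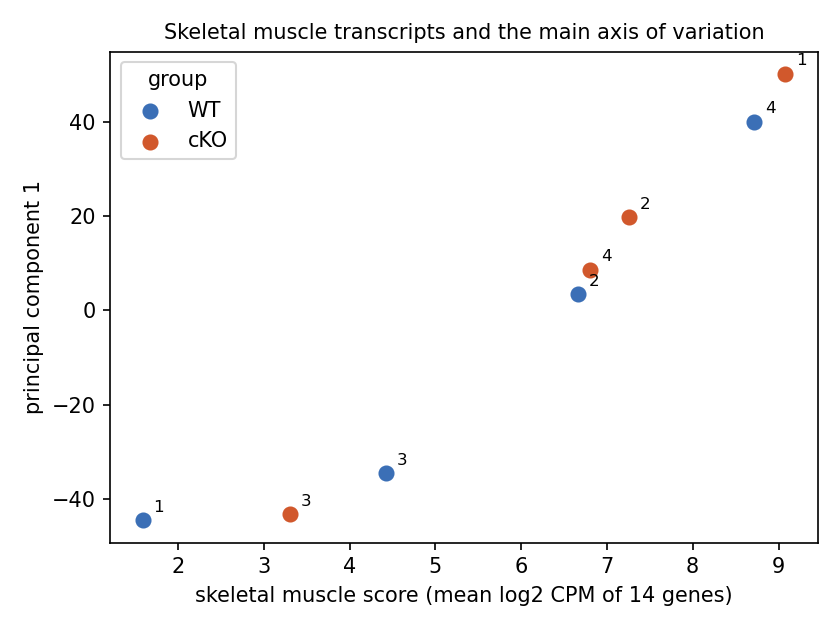
Skeletal muscle score (x axis, mean log2 CPM of 14 muscle genes) against the first principal component (y axis, 39.1% of the variance) for the 8 libraries, coloured by group and numbered by replicate. Both groups spread along the same line, from 1.59 to 9.08 on the score, with r = 0.970.

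Among the other marker lists edgeR called 0 members over all genes and 0 when adjusted over the list alone, with 4 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Interferon-stimulated genes had the lowest median, -0.32 with 10 of 11 negative (camera adjusted p = 0.120). They were called under 6 of 24 alternatives, among them those without WT replicate 2 (-0.32, camera adjusted p = 0.0302), WT replicate 4 (-0.41, 0.00167) or cKO replicate 3 (-0.45, 0.0104) and that with WT replicate 4 moved to cKO (-0.43, 9.36e-05). They include Rsad2 with 25.0 ± 6.57 and 23.9 ± 8.85 CPM. Endothelial markers had a median of -0.12 with 9 of 10 negative (camera adjusted p = 0.120). They were called under 3 of 24 alternatives, namely those without WT replicate 1 (-0.19, camera adjusted p = 0.0358) or WT replicate 4 (-0.165, 0.0406), and that with WT replicate 4 moved to cKO (-0.17, 0.0176). They include Cdh5 with 173 ± 42.7 and 153 ± 11.3 CPM and Flt1 with 152 ± 27.8 and 145 ± 25.5 CPM. Macrophage markers (median 0.01, camera adjusted p = 0.719) included Lyz2 with 33.3 ± 4.43 and 32.005 ± 12.5 CPM and Csf1r with 12.8 ± 2.92 and 12.8 ± 3.41 CPM. Fibroblast and matrix genes (median 0.11, camera adjusted p = 0.382; called without cKO replicate 2, with a median of 0.22 and adjusted p = 0.0250) included Col3a1 with 242 ± 56.2 and 235 ± 75.9 CPM and Col1a2 with 120 ± 18.1 and 110 ± 41.4 CPM. Mural cell markers (median -0.12, camera adjusted p = 0.464) included Rgs5 with 340 ± 46.6 and 355 ± 34.7 CPM and Cspg4 with 82.7 ± 10.4 and 78.5 ± 8.08 CPM.

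Schwann cell and nerve markers (median -0.18, camera adjusted p = 0.969; with WT replicate 4 moved to cKO the list was called, with a median of 0.49 and adjusted p = 0.0351) included Mbp with 36.9 ± 8.49 and 35.4 ± 5.81 CPM and S100b with 28.6 ± 5.16 and 31.5 ± 4.01 CPM. Erythrocyte markers (median -0.20, camera adjusted p = 0.584) included Hbb-bs with 343 ± 93.2 and 294 ± 66.0 CPM and Hba-a2 with 269 ± 71.7 and 274 ± 73.0 CPM. Proliferation genes (median -0.09, camera adjusted p = 0.382) included Mki67 with 1.54 ± 0.841 and 1.45 ± 0.800 CPM and Top2a with 1.80 ± 0.699 and 1.17 ± 0.550 CPM. The sex-linked genes had a median of 0.07 (camera adjusted p = 0.426). Lymphocyte markers and neutrophil and mast cell markers had 2 measured members each and were not tested as lists. These were Ms4a1 with 0.746 ± 0.356 and 0.826 ± 0.252 CPM, Cd79a with 0.899 ± 0.279 and 0.625 ± 0.351 CPM, Kit with 29.9 ± 27.2 and 26.8 ± 6.07 CPM, and Mcpt4 with 0.801 ± 0.228 and 0.780 ± 0.210 CPM.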

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

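The regroupings of the libraries and the search for genes present on 1 side only were set out before their results were seen. The tests of the sum of Gm14288 and Gm14440, of the sum of Gm20390, Nme1 and Nme2, of shared sequence, of distance to the Adcy3 and Adipoq loci, of the mitochondrial transcripts and of the genes beside Adipoq were chosen only after the patterns were seen.

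In 10 of 193 group-wise comparisons, 1 library lay far from the other 3 of its group, against 9.65 by chance. WT replicate 3 had the lowest Adcy3 among controls at 61.7 CPM (others 112 to 118), the lowest Hmgcs1 at 141 CPM (others 168 to 170) and the lowest Gm14288 at 5.26 CPM (others 10.6 to 11.1). It also held the 1 count of Gm11868 among controls (0.0497 CPM). cKO replicate 1 had the lowest mitochondrial share of counts in its group at 26.8% (others 31.2% to 31.7%), the lowest mean log2 CPM of mitochondrially encoded subunits at 13.71 (others 13.97 to 14.01) and the highest Col3a1 at 348 CPM (others 189 to 211). WT replicate 4 had a mean log2 CPM of macrophage markers of 1.68 (others 2.24 to 2.31). WT replicate 1 had 121 CPM of Nrg4 (others 83.3 to 89.3), and cKO replicate 3 had 383 CPM of Hba-a2 (others 230 to 249).

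The first pattern is the set of 9 called genes other than Adcy3, of which 6 were absent from every library of 1 group (0.1 CPM or less) and present in every library of the other (0.5 CPM or more). The same held for Gm13835, making 7 genes in all. The main edgeR test did not call Gm13835, whereas DESeq2 and edgeR with a replicate block did. Random assignment of reads between copies in each library is argued against, because no other split of the 8 libraries gave more than 2 genes of that kind. By annotated position, 0 of the 9, on 6 chromosomes, lie within 20 Mb of Adcy3 or Adipoq. This cannot decide on inherited DNA, because reads of these genes cannot be placed with certainty and a Cre transgene could lie elsewhere. The closest copies of Gm7049, Gm48795 and Gm11868 lie together on chromosome 9, namely Me1 (from 86581371) and Cyb5r4 (from 87022014). Zfp949, which DESeq2 called, lies near them (from 88548020). The closest copies of the others lie on other chromosomes. A candidate explanation is that reads of near-identical copies were assigned differently in the 2 groups, since the sum of Gm14288 and Gm14440 had a log2 fold change of 0.37 with an interval that includes 0 (-0.25 to 0.98). With Gm20390 set aside, 6 of 6 others were mostly shared, against 869 of 14544 other tested genes (Fisher exact p = 4.65e-08). This cannot favour assignment over other explanations. All but Gm48795 are processed pseudogenes, which resemble their parent genes whatever the cause, and Gm48795 overlaps Gm7049. For Gm20390 it stays open whether reads shared with Nme1 and Nme2 were assigned differently. The sum of the 3 genes was also lower (log2 fold change -0.44, 95% interval -0.71 to -0.16) but short of the threshold (edgeR adjusted p = 0.785). Sequence variants elsewhere that differ between the groups, and an effect of Adcy3 loss on these loci, stay open as untested.

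The second pattern is the higher level of mitochondrially encoded transcripts in cKO (median log2 fold change 0.36). A trend with transcript length is argued against as the whole cause, since the median was 0.44 with that trend removed. So are reads shared with nuclear copies of the mitochondrial genome (0.40 with counts summed over near-identical copies) and skeletal muscle in the dissected tissue (0.38 with the muscle score as a covariate), and camera called the list each time at the preset correlation, but without these corrections the call was lost with an estimated correlation (camera adjusted p = 0.338) and by fry (adjusted p = 0.116). The list's mean log2 CPM did not overlap between groups (13.56 ± 0.12 in WT, 13.92 ± 0.14 in cKO, SD, n = 4; exact permutation p = 0.0286, the smallest possible, and 0.429 adjusted over 30 lists), and the same held for secreted factors of brown fat (3.66 ± 0.17 and 4.00 ± 0.11, the same p-values), which camera did not call. An effect of the knockout and a difference in how the tissues were handled both stay open, untested.

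The third pattern is the higher level of genes beside Adipoq, whose promoter drives the Cre, in cKO, and whether extra copies of genes carried next to Adipoq in the Cre transgene contribute stays open. The 7 measured genes within 100 kb had a mean log2 fold change of 0.39 (as high in 0.458% of 14406 runs of 7 neighbouring genes), but 4 of them belong to the list that shows the pattern, and without B630019A10Rik (1.29) the mean was 0.24. A trend with transcript length is argued against (list median 0.41 with it removed). Eif4a2 stood at 377 to 413 CPM in the cKO libraries and at 226 to 312 CPM in the controls, and WT replicate 4, whose genotype entry carries the Cre, had 312 CPM. Its Kng2 (59.3 CPM) lay within the cKO range of 49.2 to 71.6 CPM and above the other controls (40.4 to 40.7 CPM). Over the whole list, however, the mean log2 CPM of WT replicate 4 was 3.37, below the cKO libraries (3.54 to 4.34) and within the range of the other controls (3.31 to 3.95). An effect of the knockout stays open, untested, and the call was lost without cKO replicate 3 (median 0.14, camera adjusted p = 0.0729), with WT replicate 4 moved to cKO (0.16, 0.0701), with an estimated correlation (0.338) and by fry (0.116).

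Regrouping the 8 libraries gave 35 splits into 4 and 4. For all changed genes, 1 of the 35 splits, the real one, gave as many as 10 (highest of the others 3), and for genes higher in cKO 1 of the 35 gave as many as 7 (highest of the others 3). Chance is therefore argued against for both counts but not excluded, since 1 of 35 is the smallest share possible and the counts were not adjusted. Apart from Adcy3, both counts consist of genes of mostly shared sequence, whose reads cannot be placed with certainty. Whether these counts measure a response to the knockout therefore stays open. For genes lower in cKO, 3 of the 35 gave as many as 3 in 1 direction (highest of the others 3), so chance cannot be excluded for that count. For gene lists, 30 of the 35 gave as many as 3 called lists (highest of the others 13), so chance cannot be excluded for the number of called lists. These calls used the preset correlation of 0.01. In the real split the estimated correlation was 0.987 for skeletal muscle, 0.703 for interferon-stimulated, 0.639 for endothelial, 0.540 for heat shock and 0.443 for cholesterol synthesis genes. It was lower in other lists, down to -0.0641 for secreted factors. The other splits were not repeated with estimated correlations, so why they gave so many calls was not tested.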

How the results depend on the processing

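The muscle, shared-sequence and length alternatives were chosen after seeing the data. Adcy3 kept its direction under all 23 alternatives (log2 fold change -2.44 to -1.26) and its call under all but 2, namely the replicate block (-2.23, edgeR adjusted p = 0.225) and WT replicate 4 moved to cKO (-1.26, edgeR adjusted p = 0.747). Leaving out 1 library at a time gave 8 to 14 changed genes, 6 to 9 higher and 2 to 5 lower, Adcy3 at -2.44 to -2.18 and 3 to 7 called lists. Other counts outside 1.5 times the main ones were as follows. The DESeq2 Wald test called 46 genes (20 higher, 26 lower), and no filter gave 93 genes (42 higher, 51 lower) and 6 lists. Quality weights in limma-voom gave 7 lower genes, and upper quartile factors 6 lists. The replicate block gave 1 lower gene and 5 lists. With WT replicate 4 moved to cKO, 1 gene was called (0 higher, 1 lower) with 8 lists, and the Schwann cell and nerve list reversed to a called median of 0.49. The muscle covariate gave 5 lists, and leaving out the libraries richest in muscle gave 5 lower genes and 6 lists. With counts summed over near-identical copies, and with only mostly unshared genes, 1 gene was called (0 higher, 1 lower), since the 9 others are merged or left out. The estimated correlation gave 0 lists and fry 0. Otherwise the cause was not tested. Over all genes, correlations of same-numbered libraries ran from -0.464 to 0.409, and 1 of 8 libraries was closest to its own number. This check cannot exclude a pairing by number, because the main axis of variation followed the muscle score. WT and cKO replicate 3, which correlated at 0.409, were also the libraries with negative slopes with transcript length (-0.145 and -0.0919). Whether the calls lost under the block reflect such a pairing or a weaker effect stays open. Of single named genes, 1421 values stayed on their side of the threshold and 21 lost a call. Of lists, 671 stayed, 34 gained a call, 8 lost one and 1 reversed. In the simulation with 4 libraries per group, 7.46% of 1.5-fold and 55.2% of 2-fold changes were recovered. The simulation gave 110 calls against 10 in the data, which makes its adjusted threshold more lenient. Many changes of 2-fold may therefore be missed as well.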

Other observations

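Some genes of interest fell short of edgeR's threshold over all genes but were among the 46 genes that DESeq2 called, and they were chosen after their values were seen. edgeR without a count filter called both genes given here, and Ddit4 was also called by limma-voom with library quality weights and by edgeR without cKO replicate 1 or without the 2 libraries richest in muscle transcripts, whereas limma-voom without weights called neither. Ddit4, a stress-induced inhibitor of mTORC1 signalling, stood at 59.3 ± 16.9 CPM in WT and 25.8 ± 5.14 CPM in cKO (log2 fold change -1.20, edgeR adjusted p = 0.119). Zfp949, a zinc finger gene, stood at 5.71 ± 0.633 and 10.1 ± 0.991 CPM (log2 fold change 0.83, edgeR adjusted p = 0.169). In both genes the 4 cKO libraries did not overlap the 4 WT libraries.

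The following values were also chosen after they were seen, and none of these 4 genes passed edgeR's test over all genes, whereas DESeq2, limma-voom with library quality weights and edgeR without a count filter each called Rps21 and Ndufs6, and no alternative called the 2 others. Rps21 had 57.1 ± 1.74 CPM in WT and 38.7 ± 4.51 CPM in cKO (edgeR adjusted p = 0.183), and Ndufs6 had 123 ± 19.0 and 80.9 ± 8.19 CPM (edgeR adjusted p = 0.393). Cox8b and Cox7a1, subunits enriched in brown fat and muscle, had log2 fold changes of -0.41 and -0.38 (edgeR adjusted p = 0.882 and 0.844). By transcript length, among 6255 nuclear protein-coding genes with a mean log2 CPM over 4, the median log2 fold change was -0.13 for 239 genes of 501 to 1000 bases, with 174 negative, and 0.06 for 1713 genes over 5000 bases, with 583 negative. The slope with length was -0.145 in WT replicate 3 and -0.0919 in cKO replicate 3, against 0.0101 to 0.0732 in the other 6 libraries. Mean slopes were -0.0258 ± 0.0795 in WT and 0.0258 ± 0.0789 in cKO (log2 per doubling of length, two-sided exact permutation p = 0.429, n = 4 each).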
